A study of Leishmania donovani with 16 samples.

How the data were processed

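The study followed cultures of the protozoan parasite Leishmania donovani, strain 1S, as the insect-stage form, the promastigote, was turned into the intracellular form, the amastigote, without host cells. Per the labels' protocols, promastigotes grew at 26 °C in Medium 199 with 10% fetal calf serum, and differentiation was started by moving them to 37 °C and pH 5.5 together. Total RNA taken with Trizol at 0, 2.5, 5, 7.5, 10, 15, 24 and 144 h was labelled with Cy3 and hybridised by NimbleGen, 1 sample per array. The labels describe the 2 replicates of each time as independent biological replicates, which gives 16 arrays in 8 groups of 2.

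Groups were taken from the sample titles, which match the life cycle labels. The source name label differs from both for 4 of the 8 times: it exchanges 7.5 h with 10 h and 15 h with 24 h in both replicates. The exchange was run as an alternative. The last group is 144 h in the titles, while the extraction protocol gives 2 weeks for the fully formed amastigotes, and the titles were followed.

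The scanner files hold 1 raw intensity per spot, not background corrected or normalized, written by NimbleScan 2.3.78 per the file headers. Each array carried 389307 spots. There were 8209 features with 10 probes, the number that the series description gives for open reading frames, and 151 features with 3 probes, the number that it gives for structural RNAs. A further 536 features had 2 probes and 3 had 1 probe, and the labels do not say what these are. Every such probe was spotted 3 times. Another 134146 probes, about 100 bp apart, tiled 8517 regions that the files name by chromosome, start and end on version 2.0 of the LinJ assembly of Leishmania infantum, the related species on whose sequence the array was designed. These regions do not overlap. Of the 8375 gaps between neighbouring regions, 91.3% were a multiple of 3 bp long, against 33.3% by chance, and the median gap was 1371 bp. The files do not say what the regions hold, and the probes' strand is not given in the sources used here. The arrays also held 4307 probes of random sequence, used as a measure of background.

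The feature IDs were paired with no gene names. None of the 8899 feature IDs (0 matched) occurred in the reference gene table, whose 8123 genes belong to the assembly of another strain. The product-name lists fixed in advance could therefore not be applied, and no result is given for them. At most 2 feature IDs that rose and 2 that fell are printed, as the rule says. Tiled regions, which have coordinates, were named by the same rule, extended to them after the data were examined. The rule takes the 12 largest rises and 12 largest falls between 144 h and 0 h, 6 and 6 for 24 h, 2.5 h and the transient contrast, and 2 and 2 for other contrasts, among regions past the threshold that changed the same way in both replicates. It left out 106 regions divided into parts.

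Raw intensities were corrected with limma's normexp method with an offset of 50, which was fitted on all spots, then put on the log2 scale and quantile normalized without the random-sequence probes. The 3 spots of a probe were averaged, and the probes of a feature or region were summarised by median polish. All changes are differences of these log2 values. One linear model with a mean per time was fitted to all 16 arrays with lmFit and eBayes (limma 3.58.1 in R 4.3.3), without a block, with 8 residual degrees of freedom. Contrasts were each time against 0 h, each time against the one before, all times together (F-test), and the mean of 5, 7.5, 10 and 15 h against the mean of 0 and 144 h. A transient call also required the same direction against 0 h alone and against 144 h alone. P-values were adjusted by Benjamini-Hochberg within each contrast over the 8209 features with 10 probes, over the 8327 tiled regions with at least 3 probes, or over all 8899 features for the shorter classes. The threshold was an adjusted p of 0.05. Standard errors of changes (SE) come from the moderated spread of the same model. Sets of features were compared with all others by camera with a preset correlation of 0.01, and again with an estimated correlation.

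A region at or below the 95th percentile of the random probes on every array of a group is given a bound: the mean of the brighter group against the higher of that percentile and the region's own value. Median raw intensity ranged from 724.6 to 1747.9 per array and the random probes' 95th percentile from 191.7 to 337.4. Between 88.1% and 98.3% of spots exceeded that percentile. The number of arrays, not the number of spots, limits the precision, and all p-values rest on 2 replicates per time.

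Scan day, from the file headers, was tested as a batch. Replicate 1 of every time was scanned on day 1, replicate 2 of 0, 2.5 and 5 h on day 2, and replicate 2 of the later times on day 3. A fit with scan day as a block, added after the data were examined, is given beside the counts. Within day 1 each time has 1 array, so that changes in replicate 1 are given without a test. The numbers of the replicates were also checked for pairing; that check is given with the alternatives.

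On data simulated from these features with 200 changed ones, the model recovered 14.9% of changes of log2 0.5, 63.6% of those of 1 and 94.8% of those of 2 for 144 h against 0 h over 8209 features, with 5.6% false among its calls. When the raw signal of 200 features was multiplied by 2 on the 144 h arrays, the whole chain returned a median log2 change of 1.16. A change of log2 1 put into the transient contrast of such simulated features was recovered for 91.5% of them. Noise in the simulations was drawn independently for each feature and array. It leaves out the deviations that arrays with the same replicate number shared, so the simulated percentages need not hold for the real arrays.

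The deposited value table holds 8178 values per array on a linear intensity scale. The submitters' processing notes name RMA, and no other step or centring is given in the sources used here. Its numeric row IDs match none of the feature IDs. Its log2 medians ran from 8.83 to 9.05 against 9.60 to 9.71 in the values used here, and sorted values correlated at 0.992 to 0.997 on the same array. It was used only as an alternative for counts and for replicate agreement.

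Alternatives fixed before the data were examined were no background correction, an offset of 0, median scaling, cyclic loess, the mean of probes, a filter on dim features, the deposited value table, a replicate block, a trended robust prior, the exchanged times, leaving out each array, fitting only the 4 arrays compared, and stricter thresholds. A scan-day block, a correction for feature size and a fit without the 5, 7.5 and 10 h arrays were added after the data were examined.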

Results

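RNA levels were measured on 16 one-colour arrays through the change of Leishmania donovani promastigotes into axenic amastigotes. Each of the 8 times had 2 replicates, which the labels describe as independent. The design asks which transcripts change, and when, between the start of heat and acid exposure and the fully formed amastigote. Median raw intensity per array ranged from 724.6 to 1747.9, and 88.1% to 98.3% of spots on an array were brighter than the 95th percentile of its random-sequence probes. Of the 8209 features with 10 probes each, 1060 (12.9%) changed at some time by limma's F-test, and 219 of 8327 tiled regions (2.6%) did. The F-test weighs all times together, and single contrasts were adjusted separately, so these are not totals of all that changed. The contrast of 144 h with 0 h alone called 2278 features and 871 regions. With the scan day as a block the F-test count of 10-probe features was 1514. With 1 array left out, the F-test called 294 features without 144 h replicate 1, 363 without 144 h replicate 2, 471 without 0 h replicate 1, 515 without 0 h replicate 2, 609 without 2.5 h replicate 2, 626 without 2.5 h replicate 1 and 671 without 15 h replicate 1, and up to 1345 without 5 h replicate 2.

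**Figure D1:**
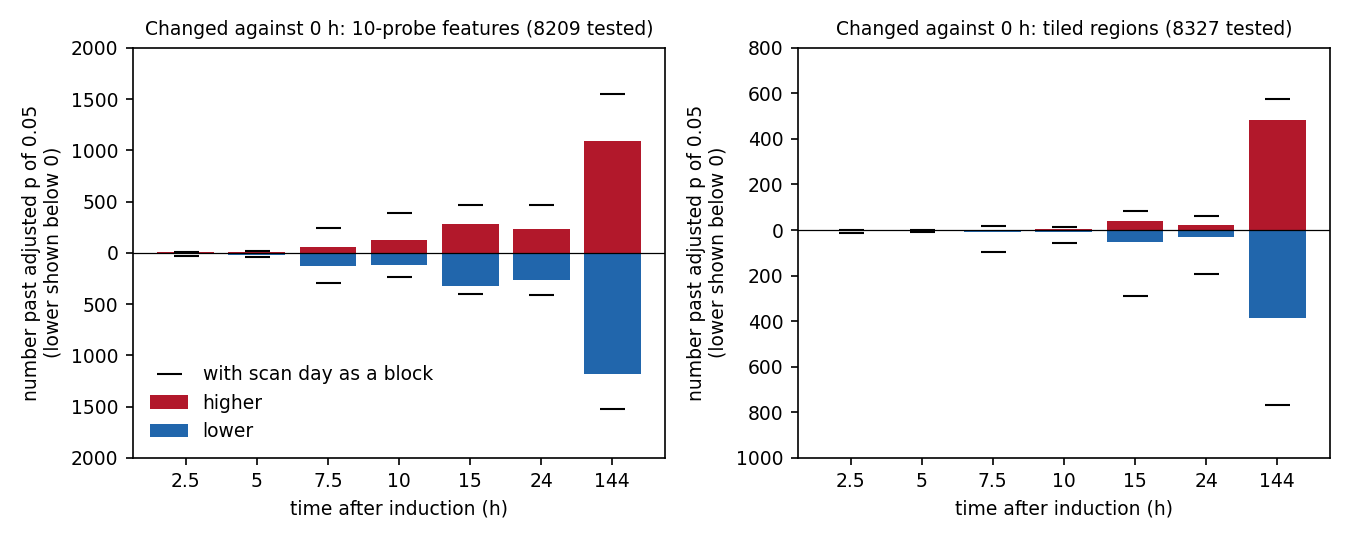
Number of 10-probe features (left) and tiled regions (right) higher (red) or lower (blue) than at 0 h at each time, with 2 arrays per time, and the same counts with scan day as a block (black dashes). Calls against 0 h rose from 22 features at 2.5 h to 2278 at 144 h, and from 5 to 871 regions.

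Amastigotes at 144 h differed most from promastigotes. The largest rise was in feature LINFS0004828, whose mean log2 intensity went from 10.00 ± 0.61 to 14.97 ± 0.10 (SD, n = 2), a 31.4-fold increase. Feature LINFS0005541 rose 16.6-fold, from 11.28 ± 0.22 to 15.34 ± 0.43. Feature LINFS0000610 fell from 12.76 ± 0.03 to 9.51 ± 0.30, 9.56-fold lower in amastigotes, and LINFS0004964 from 12.32 ± 0.32 to 9.60 ± 0.22, 6.56-fold lower. Adjusted p was 0.000406, 0.000257, 6.29e-05 and 7.85e-05 in that order, and within replicate 1 the log2 changes were 5.33, 4.51, −3.03 and −2.64. The files pair no gene name with these IDs.

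In all, 1095 of the 10-probe features were higher and 1183 lower at 144 h than at 0 h, 27.8% of those tested. Of these, 277 rose and 413 fell at least 2-fold. The 2 replicates gave changes that correlated at r = 0.787 (Spearman 0.746) across features, which are not independent replicates, and 77.4% of features had the same sign in both. With scan day as a block, 1544 were higher and 1522 lower, and with median scaling 1515 and 1234, so that which direction had more features depended on the setting. Leaving out 1 of the 4 arrays lowered the total to 1006 without 0 h replicate 1, 1259 without 144 h replicate 1, 1414 without 0 h replicate 2 and 1511 without 144 h replicate 2. On both 144 h arrays the last probe of a feature was less bright relative to its first probe (mean log2 difference 0.075 and −0.023) than on the 0 h arrays (0.205 and 0.215). On the other arrays it lay between 0.165 and 0.203 at 2.5 h and 5 h and between 0.035 and 0.143 from 7.5 h to 24 h. The change also followed feature size, with a median log2 change of −0.15 in the decile of features whose last probe lay nearest the first position and 0.23 in the decile where it lay farthest.

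Tiled regions have positions on chromosomes, but the sources used here do not tie them to the features. At 144 h, 483 regions were higher and 388 lower than at 0 h. The largest rise was on chromosome 22 from 250715 to 251909, where the mean log2 intensity went from 9.57 ± 0.07 to 13.60 ± 0.09 (SD, n = 2), 16.3-fold higher. The region on chromosome 8 from 502746 to 504473 rose 11.6-fold (log2 3.54, SE 0.30), and that on chromosome 26 from 638709 to 638996, with 3 probes and above the random probes on 1 of the 2 arrays at 0 h, rose by log2 3.20 (SE 0.36), or by 2.16 with the mean of all probes and 3.82 with an offset of 0. Chromosome 22 held another rising region from 300490 to 304555, 5.78-fold higher. On chromosome 35 the regions from 297626 to 305167 and from 210986 to 216669 rose 5.02-fold and 4.80-fold. Regions on chromosome 34 from 1313655 to 1317668 and chromosome 15 from 607870 to 609291 were 4.38-fold and 4.33-fold higher. Adjusted p was 0.00194 or smaller for each of these. A 3-probe region on chromosome 36 from 1120633 to 1120942 passed at an adjusted p of 0.0481 (log2 2.29), and that call ended without 0 h replicate 1 (1.99), 144 h replicate 1 (2.78), 0 h replicate 2 (2.59) or 144 h replicate 2 (1.81). It also ended with an offset of 0 (adjusted p of 0.0525), median scaling (0.061), cyclic loess (0.0643) or without the 6 arrays of 5, 7.5 and 10 h (0.0539).

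On chromosome 27, 3 neighbouring regions were higher from 15 h on. The region from 838585 to 857616 lay below the 95th percentile of the random probes on both 0 h arrays, with a mean log2 intensity of 7.30, and reached 10.28 ± 0.04 (SD, n = 2) at 144 h, at least 6.64-fold higher. The regions from 859432 to 870220 and from 894116 to 899824 rose by log2 2.74 (SE 0.38) and 3.43 (SE 0.50), the latter from above the random probes on 1 of the 2 arrays at 0 h. With the mean of all probes in place of median polish, the 3 log2 rises at 144 h were smaller, 2.01 (4.03-fold), 1.87 and 2.58 in order of position. Adjusted p at 144 h was 0.00181, 0.00121 and 0.00143. Their changes from 24 h to 144 h did not pass the threshold (adjusted p of 0.775, 0.841 and 0.624).

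**Figure D2:**
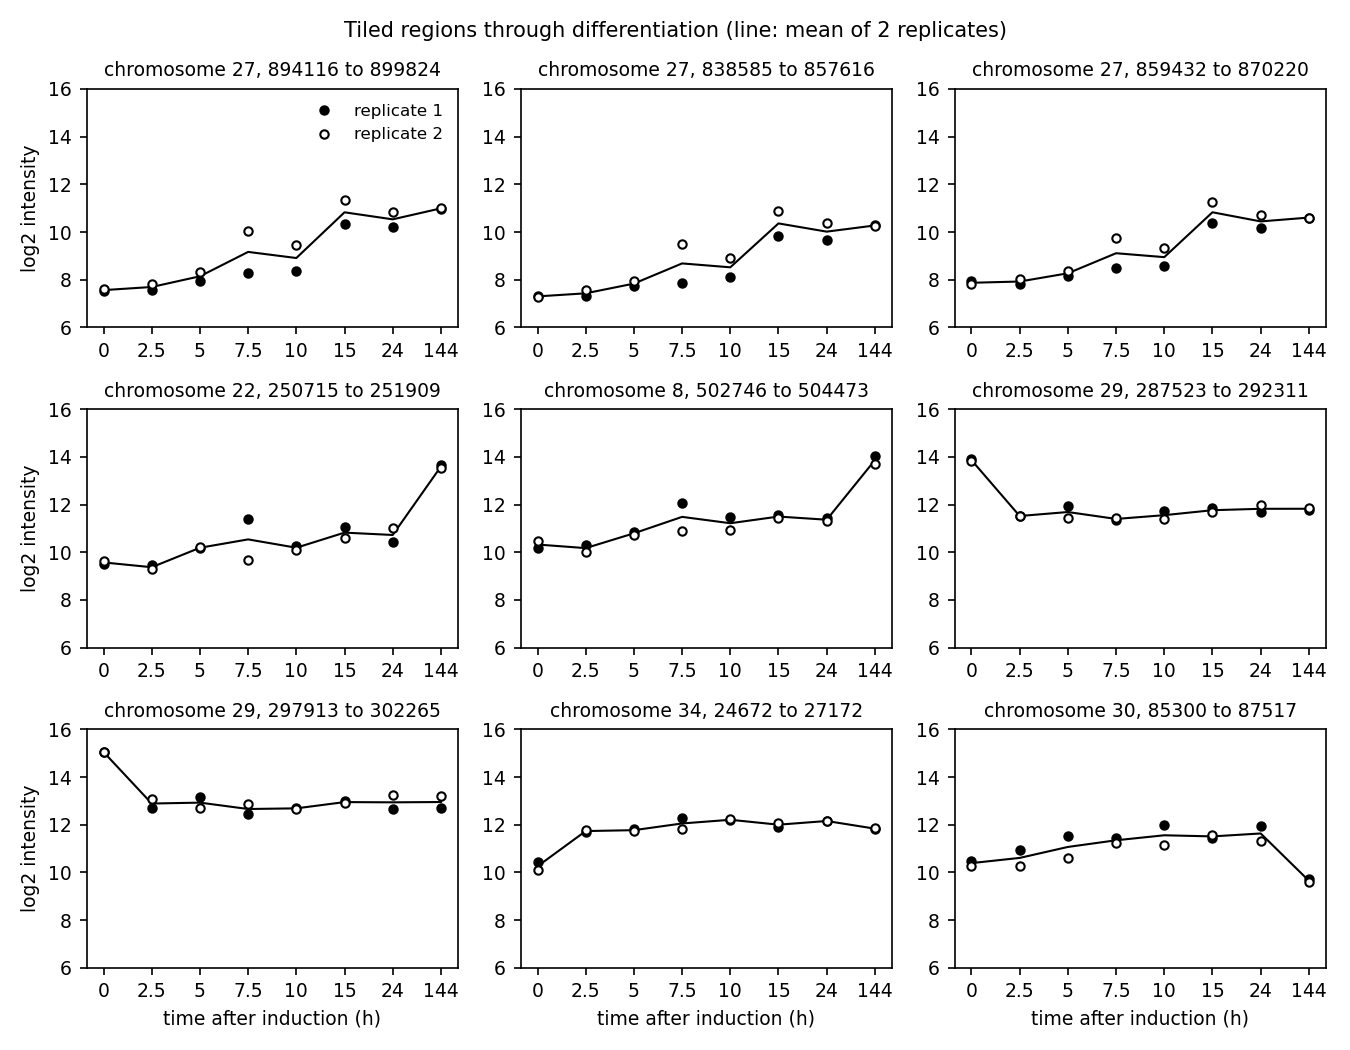
Normalized log2 intensity of 9 tiled regions at the 8 times, with filled points for replicate 1, open points for replicate 2 and a line through their mean. The chromosome 27 regions rose by 15 h, those on chromosomes 22 and 8 rose mainly after 24 h, and those on chromosomes 29 and 34 changed by 2.5 h.

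Among falling regions, the largest change at 144 h was on chromosome 4 from 98398 to 99822, where log2 intensity fell by 2.24 (SE 0.28), or by 1.52 with the mean of all probes. The region on chromosome 35 from 374792 to 375893 fell by 2.13 (SE 0.31), and those on chromosome 29 from 297913 to 302265 and from 287523 to 292311 changed by −2.10 (SE 0.24) and −2.04 (SE 0.19). Chromosome 36 from 119775 to 125730 and chromosome 20 from 540278 to 543082 were 4.26-fold and 4.10-fold lower. Chromosome 31 held 3 of the 12 regions, from 442823 to 447163, from 144942 to 148081 and from 91883 to 96499, with log2 changes of −1.83, −1.82 and −1.75. The other regions named were on chromosome 33 from 716194 to 716639 (fell by 2.09), chromosome 34 from 950088 to 952096 (fell by 1.91) and chromosome 23 from 326134 to 329734 (fell by 1.83). Adjusted p lay between 0.000123 and 0.00867 over these 12. The chromosome 33 region, with 3 probes, no longer passed without 144 h replicate 1 (−1.69) or without 0 h replicate 2 (−1.87). With scan day as a block 575 regions were higher and 767 lower, and with median scaling 310 and 313. The total of 871 was 219 without 0 h replicate 1, 248 without 0 h replicate 2, 350 without 144 h replicate 1 and 414 without 144 h replicate 2.

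Features with 3 probes, the number that the series description gives for structural RNAs, rose as a class at 144 h. Of the 151, 74 were higher and 1 was lower in the test over all features, and 85 were higher and 1 lower adjusted over the list alone. Their median log2 change was 0.93, with quartiles of 0.36 and 1.59, against −0.01 for the 10-probe features, a shift of 0.94 or 1.92-fold. Median levels of the class were 11.25 and 11.22 on the 0 h arrays and 12.80 and 12.74 on the 144 h arrays. Camera gave an adjusted p of 3.54e-15 with the preset correlation and an adjusted p of 0.0158 with an estimated correlation. With scan day as a block the shift was 0.93, and within scan day 1, with 1 array per time and no test, the median level went from 11.25 to 12.80. The same 144 h arrays had a less bright last probe relative to the first (0.075 and −0.023) than the 0 h arrays (0.205 and 0.215). At 15 h the shift was 0.26, with an adjusted p of 0.000438 at the preset correlation and an adjusted p of 0.116 with an estimated correlation. At 24 h the shift was 0.18, with an adjusted p of 0.00738 at the preset correlation and an adjusted p of 0.208 with an estimated correlation. The 536 features with 2 probes, whose nature the labels do not give, had 56 higher and 50 lower at 144 h and a shift of 0.04 (adjusted p of 0.785 by camera, and 0.845 with an estimated correlation). That class was shifted lower at 2.5 h by −0.14 (adjusted p of 1.46e-05 with the preset correlation and an adjusted p of 0.0215 with an estimated correlation). At 10 h its shift was −0.24 (adjusted p of 3.43e-05 with the preset correlation and an adjusted p of 0.0215 with an estimated correlation). Of the single 2-probe features, 0 were called at 2.5 h, and 7 were higher and 7 lower at 10 h. The class shifts at 5, 15 and 24 h were −0.15, −0.16 and −0.22 and passed by camera only with the preset correlation. With an estimated correlation their adjusted p was 0.0511, 0.161 and 0.0633.

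**Figure D3:**
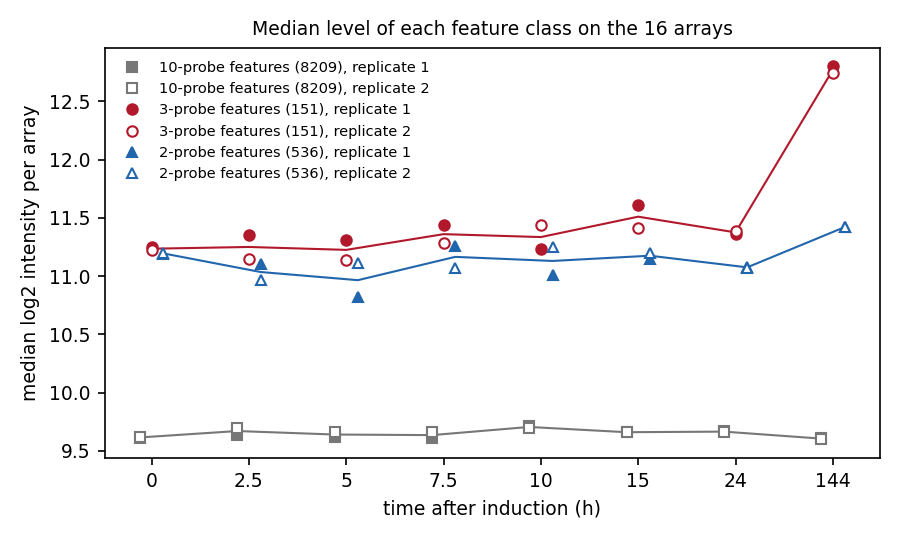
Median normalized log2 intensity on each array for features with 10 (grey squares), 3 (red circles) and 2 (blue triangles) probes, with filled symbols for replicate 1, open ones for replicate 2 and lines through the means. The 3-probe class lay between 11.14 and 11.61 on all arrays up to 24 h and at 12.80 and 12.74 at 144 h.

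Chromosomes were compared because they can vary in copy number in cultured Leishmania and are transcribed in long units. The regions of chromosomes 8 and 12 were higher at 144 h than those of the rest, with median log2 shifts of 0.22 and 0.26, and 25 of 124 and 23 of 96 of their regions passed as higher. Both had an adjusted p of 9.05e-05 with the preset correlation over 36 chromosomes, and neither passed with an estimated correlation (adjusted p of 0.991 for both). With it, camera gave 0 of 36 chromosomes, and 0 at an unadjusted p under 0.05. Shifts were positive within replicate 1 (0.36 and 0.32) and replicate 2 (0.17 and 0.22), and the same number of chromosomes, 2, passed with scan day as a block. Without 0 h replicate 1 the number was 4, and without 144 h replicate 2 it was 5. At 24 h the shifts were 0.02 and 0.11.

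Along chromosomes, 657 windows of 50000 bp with at least 5 regions were compared at 144 h, a test added after the values were seen. Camera called 12 higher and 2 lower with the preset correlation. With an estimated correlation camera called 0, with a smallest adjusted p of 0.998, and 21 windows had an unadjusted p under 0.05. That is fewer than the share of 0.05 of the 657 windows that chance alone would give. Among windows past the threshold only with the preset correlation, that on chromosome 8 from 300001 to 350000 had a median change of 2.34-fold, with 12 of its 15 regions called higher. Medians were 2.79-fold on chromosome 22 from 600001 to 650000, 2.46-fold on chromosome 29 from 600001 to 650000, 2.36-fold on chromosome 34 from 650001 to 700000 and 2.18-fold on chromosome 12 from 1 to 50000. The 2 lower windows lay on chromosome 33 from 1500001 to 1550000 and chromosome 35 from 800001 to 850000, with median log2 changes of −0.63 and −0.42.

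**Figure D4:**
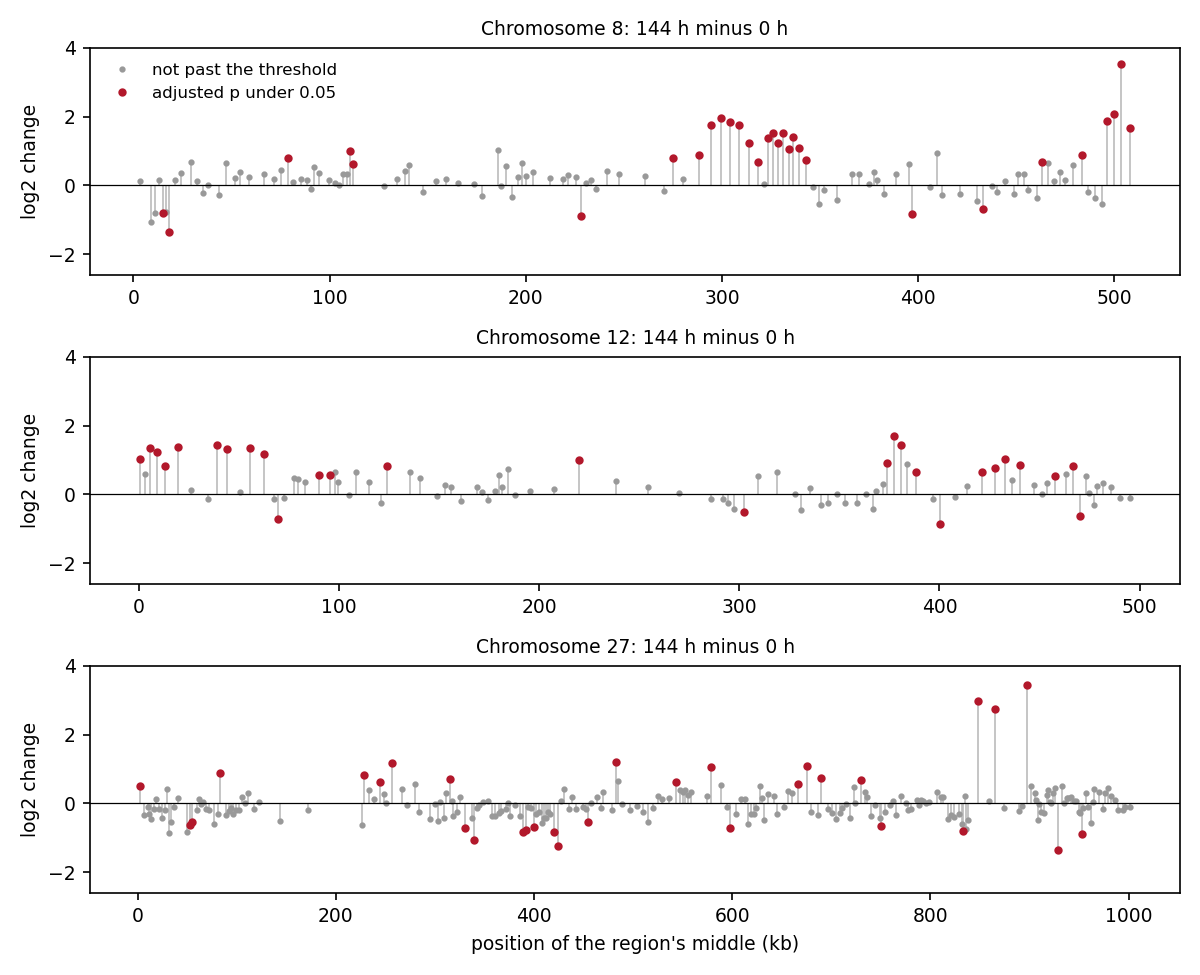
Log2 change of each tiled region between 144 h and 0 h along chromosomes 8, 12 and 27, at the middle of the region in kb, with regions past the threshold in red. Chromosome 8 shows a run of regions that were higher between 250001 and 350000, chromosome 12 one from its start, and chromosome 27 the 3 regions that lie between 838585 and 899824.

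At 2.5 h, where the question is which transcripts respond at the onset of heat and acid, 5 tiled regions were called, and 13 with scan day as a block. Regions on chromosome 29 from 287523 to 292311 and from 297913 to 302265 changed by log2 −2.34 (SE 0.19) and −2.16 (SE 0.24). Those on chromosome 4 from 98398 to 99822 and chromosome 24 from 818158 to 820668 changed by −2.08 (SE 0.28; −1.42 with the mean of all probes) and −1.44 (SE 0.15). The region on chromosome 34 from 24672 to 27172 rose by 1.48 (SE 0.17). Adjusted p was 0.0102 or smaller in each, and all 5 were also past the threshold at 144 h, with log2 changes of −2.04, −2.10, −2.24, −0.82 and 1.58. LINFS0004964 was 1 of the 16 features with 10 probes that were lower at 2.5 h (log2 −1.98, adjusted p of 0.00474), and 6 were higher. The total of 22 was 36 with scan day as a block, 3 without 0 h replicate 2, 4 without 2.5 h replicate 2, 7 without 2.5 h replicate 1 and 8 without 0 h replicate 1. The chromosome 4 region missed the threshold without 0 h replicate 2 (adjusted p of 0.0512), 2.5 h replicate 1 (0.0961) or 2.5 h replicate 2 (0.242), the chromosome 34 region without 0 h replicate 2 (0.0522) or 2.5 h replicate 2 (0.063), and the chromosome 29 region from 297913 without 2.5 h replicate 1 (0.0549). With only the 4 arrays of 2.5 h and 0 h fitted, the regions on chromosomes 34, 4 and 24 missed it (0.0673, 0.294 and 0.0523).

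At 5, 7.5 and 10 h the same chromosome 29 regions and the chromosome 34 region from 24672 to 27172 were past the threshold. At 10 h the chromosome 29 regions were 4.96-fold and 5.15-fold below their 0 h level, and the chromosome 34 region was 3.86-fold above it. The region on chromosome 34 from 1313655 to 1317668 was higher by log2 1.62 (SE 0.25) at 7.5 h and 1.67 (SE 0.25) at 10 h, with an adjusted p of 0.0245 and 0.016. It missed the threshold at 7.5 h without 0 h replicate 1 (1.51), 0 h replicate 2 (1.73) or 7.5 h replicate 1 (1.38), and at 10 h without 0 h replicate 1 (1.56), 0 h replicate 2 (1.78) or 10 h replicate 1 (1.40). Median scaling also ended both calls (adjusted p of 0.176 and 0.115). At 5 h the chromosome 4 region from 98398 to 99822 was named too, with a log2 change of −2.13, or −1.52 with the mean of all probes. It missed the threshold without 5 h replicate 1 (−2.05) or 5 h replicate 2 (−2.21). When only the 4 arrays of 5 h and 0 h were fitted, all 3 regions named at 5 h missed it. The adjusted p was 0.724 for chromosome 34 from 24672 and 0.512 for chromosome 29 from 287523. With only the 4 arrays of 10 h and 0 h, the chromosome 34 regions from 24672 (0.0826) and from 1313655 (0.287) missed it.

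Among 10-probe features, 4 were higher and 17 lower at 5 h, 53 and 125 at 7.5 h, and 124 and 115 at 10 h. With scan day as a block 16 were higher and 44 lower at 5 h, 239 and 293 at 7.5 h, and 388 and 236 at 10 h. The deposited value table gave 143 higher and 113 lower at 7.5 h, so that the excess of lower features there was not kept. At 10 h it gave 138 and 169, cyclic loess 147 and 151, and the size correction 119 and 196. Under the exchange of times in the source name label, 124 were higher and 115 lower at 7.5 h, and 53 and 125 at 10 h. At 5 h the total was 8 without 0 h replicate 2, 9 without 0 h replicate 1 and 11 without 5 h replicate 1. At 7.5 h it was 18 without 0 h replicate 1, 21 without 7.5 h replicate 1 and 28 without 0 h replicate 2. At 10 h it was 19 without 0 h replicate 1, 23 without 0 h replicate 2, 26 without 10 h replicate 1 and 138 without 10 h replicate 2.

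At 15 h and 24 h the chromosome 27 regions had the largest log2 rises among called regions. The region from 894116 to 899824 was higher by log2 3.26 (SE 0.50) at 15 h and 2.97 (SE 0.50) at 24 h. The longest, from 838585 to 857616, was at least 7.05-fold higher at 15 h and at least 5.55-fold higher at 24 h, and that from 859432 to 870220 was 7.77-fold and 5.96-fold higher. With the mean of all probes the log2 rise from 894116 was 2.42 and 2.21, that from 838585 was 2.08 and 1.84, and that from 859432 was 1.78 at 24 h. On chromosome 34, the named regions at 24 h were those from 1313655 to 1317668 (3.86-fold higher), from 24672 to 27172 (3.73-fold) and from 370437 to 370797 (3.00-fold). Besides the regions on chromosomes 4 and 29, the named falls at 24 h were on chromosome 31 from 144942 to 148081 and from 1914638 to 1915247 (2.96-fold and 2.93-fold) and chromosome 9 from 554009 to 554887 (2.75-fold). Each of the 12 had an adjusted p of 0.0453 or smaller, and all 12 passed with scan day as a block.

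Most of these calls at 24 h ended when 1 array was left out. Of the 12 regions, 4 passed without 0 h replicate 1, 5 without 24 h replicate 1, 5 without 0 h replicate 2 and 3 without 24 h replicate 2, and 6 passed with only the 4 arrays of 24 h and 0 h. The chromosome 27 region from 894116 kept log2 values of 2.94, 3.28, 3.00 and 2.66 in that order, with adjusted p from 0.0999 to 0.188. At 15 h it had an adjusted p of 0.111 without 0 h replicate 1, 0.113 without 0 h replicate 2 and 0.0745 without 15 h replicate 2, and the region from 838585 had 0.111, 0.108 and 0.0665. Median scaling ended the calls of the chromosome 31 and chromosome 9 regions at 24 h (adjusted p of 0.0689, 0.0837 and 0.0638).

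In all, 280 features with 10 probes were higher and 324 lower at 15 h, and 231 and 268 at 24 h. The brightness of the last probe relative to the first was below its 0 h values at these times too, 0.035 and 0.089 at 15 h and 0.099 and 0.036 at 24 h. With scan day as a block 470 were higher and 401 lower at 15 h, and 467 and 409 at 24 h, so that the excess of lower features was not kept, and the deposited value table gave 228 higher and 210 lower at 15 h. The total at 15 h was 39 without 15 h replicate 1, 50 without 0 h replicate 1, 66 without 0 h replicate 2 and 138 without 15 h replicate 2. That at 24 h was 37 without 0 h replicate 1, 59 without 0 h replicate 2, 89 without 24 h replicate 2 and 103 without 24 h replicate 1. When only the 4 arrays of 24 h and 0 h were fitted, 6 features passed at 24 h.

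Many features called at 24 h were called the same way at 144 h. Of the 231 that were higher at 24 h, 145 were also higher at 144 h, against 30.8 for independent lists, and of the 268 that were lower, 239 were also lower, against 38.6. Only 4 were higher at 24 h and lower at 144 h. Both comparisons use the same 0 h arrays, and part of the excess may come from them. Groups simulated without change gave 0 shared calls, but as few calls are expected without change, this does not measure that part. The changes correlated at 0.61 across features, against 0.495 in that simulation, with a covariance of 0.159 against 0.034. Changes from different replicates, which share no array, correlated at 0.598 and 0.46.

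Between successive times from 2.5 h to 24 h limma called 0 of the 10-probe features and 0 of the tiled regions in each interval. At an unadjusted p under 0.05 there were 91 features between 2.5 h and 5 h, 327 between 5 h and 7.5 h, 33 between 7.5 h and 10 h, 153 between 10 h and 15 h and 1 between 15 h and 24 h. For regions these counts were 73, 130, 77, 172 and 18, and with scan day as a block 1 region passed between 10 h and 15 h. Each of these unadjusted counts is below a share of 0.05 of the 8209 features or 8327 regions, the share that chance alone would give. They are therefore no sign of change. The labels disagree on which arrays are 7.5 h and 10 h and which are 15 h and 24 h. Exchanging them also gave 0 features in each interval. Only the intervals from 5 h to 7.5 h and from 10 h to 15 h then compare other arrays. In the remaining intervals the result could not change.

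From 24 h to 144 h, 400 features with 10 probes rose and 517 fell. The largest regional rises were on chromosome 26 from 638709 to 638996 (8.26-fold, but 4.16-fold with the mean of all probes and 13.0-fold with an offset of 0) and chromosome 22 from 250715 to 251909 (7.32-fold). Chromosome 30 held the largest falls, from 85300 to 87517 (3.95-fold) and from 1741942 to 1742570 (3.56-fold). Of the tiled regions 272 rose and 112 fell, and of the 3-probe features 52 rose, with a class median of 0.71 (camera p of 9.11e-15, and p of 0.00159 with an estimated correlation). LINFS0005541 rose by log2 2.64 and LINFS0000610 fell by 2.25 over this interval (adjusted p of 0.0089 and 0.00222). With scan day as a block 868 of the 10-probe features rose and 1225 fell, as did 706 and 391 of the tiled regions. Without 24 h replicate 2 the numbers were 249 and 386, and with only the 4 arrays fitted 228 and 422. Rises outnumbered falls with cyclic loess (193 and 179), with the size correction (436 and 399) and without 144 h replicate 2 (213 and 167). The total of 917 was 29 without 24 h replicate 1, 159 without 144 h replicate 1, 380 without 144 h replicate 2 and 372 with cyclic loess. The chromosome 30 region from 85300 missed the threshold without 24 h replicate 1 (adjusted p of 0.112), 144 h replicate 1 (0.0565) or 144 h replicate 2 (0.0623). That from 1741942 missed it without 24 h replicate 1 (0.103) or 144 h replicate 2 (0.0643), and the chromosome 22 region without 24 h replicate 1 (0.0802).

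Some regions differed, on average from 5 h to 15 h, from the mean of 0 h and 144 h, with the same direction, not a threshold, required against each end. The region on chromosome 16 from 222723 to 223419 was higher by log2 1.59 (SE 0.27), and that on chromosome 1 from 74893 to 75802 by 1.42 (SE 0.25). Regions on chromosome 30 from 85300 to 87517, chromosome 31 from 676210 to 677197 and chromosome 29 from 1003651 to 1004819 were higher by 1.35, 1.34 and 1.25, and chromosome 34 from 370437 to 370797 by 1.01. The region on chromosome 15 from 45723 to 54500 was lower by 2.16-fold, and that on chromosome 22 from 604632 to 604888 by 2.15-fold. Both differences came mainly from a rise by 144 h (log2 1.36 and 1.78 against 0 h), and neither passed against 0 h from 5 h to 15 h. Lower regions also lay on chromosome 24 from 818158 to 820668 (2.13-fold) and chromosome 35 from 856124 to 856834 (2.07-fold). The chromosome 29 regions from 287523 and from 297913 met the criterion too (2.37-fold and 2.29-fold), although their changes from 24 h to 144 h were 0.00 and 0.01. Of these 12 regions, 4 passed without 0 h replicate 1, 4 without 0 h replicate 2, 6 without 144 h replicate 1 and 6 without 144 h replicate 2. The chromosome 29 region from 1003651 (adjusted p of 0.0452) and the chromosome 22 region from 604632 (0.0413) also missed the threshold in most other fits without 1 array, from 2.5 h to 24 h. All 12 passed with scan day as a block, 9 with median scaling and 10 with cyclic loess. The chromosome 29 region from 1003651 (adjusted p of 0.0735 with median scaling and 0.0515 with cyclic loess) and the chromosome 22 region (0.0715 and 0.0565) were lost under both. The chromosome 29 region from 287523 no longer met the criterion of direction with median scaling, at an adjusted p of 0.00437. Among 10-probe features 389 were higher and 181 lower, and with scan day as a block 810 and 353. Without 2.5 h replicate 1, and likewise without 2.5 h replicate 2, they were 275 and 114, and with the size correction 257 and 235. The total of 570 was 93 without 0 h replicate 2, 140 without 144 h replicate 1, 141 without 0 h replicate 1, 254 without 15 h replicate 2, 275 without 144 h replicate 2, 290 without 15 h replicate 1, 317 without 7.5 h replicate 2 and 323 without 10 h replicate 1. It was 1042 without 10 h replicate 2 and 1051 without 5 h replicate 2.

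Agreement between the 2 replicates varied with time. Changes against 0 h in replicate 1 correlated with those in replicate 2 at 0.536, 0.513 and 0.458 at 2.5, 5 and 7.5 h, at 0.735 at 10 h, and at 0.844, 0.828 and 0.787 at 15, 24 and 144 h, across 8209 features. Replicate 1 at 7.5 h was closer to replicate 2 at 10 h (0.805) than to replicate 2 at 7.5 h, and replicate 1 at 10 h correlated with replicate 2 at 7.5 h at 0.796. Judged by levels, 4 of the 8 arrays of replicate 1 had the replicate 2 array of the same time as the closest.

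**Figure D5:**
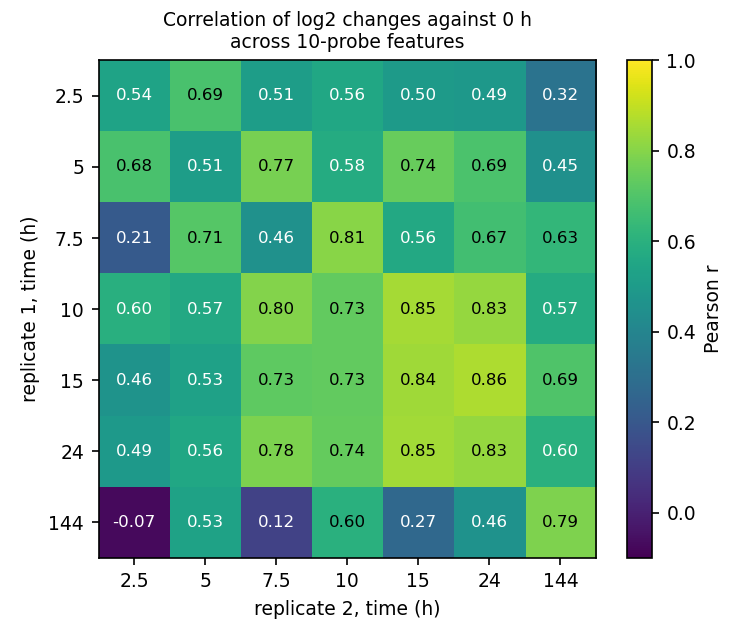
Pearson correlation, across 10-probe features, of the log2 change against 0 h in replicate 1 (vertical axis, h) with that in replicate 2 (horizontal axis, h), where colour and number give r. The highest values lie among 10, 15 and 24 h, and 7.5 h has 0.458 with itself and 0.805 with 10 h of replicate 2.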

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

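Tests here on normalization, on structural RNA in the labelled sample and on exchanged times were chosen only after the result was seen. Those on neighbouring regions, brightness and feature size draw on measures that were also added after the data were seen. The chromosomes weighed below were picked because their shift had been seen. The median log2 change of the 3-probe features from 24 h to 144 h was 0.706, and a contrast of these times itself called 52 of the 151 as higher, so that the class differed between them. Outside the main measurement, 106 of the 536 features with 2 probes (19.78%), whose nature the labels do not give, were called at 144 h. That share was below those of the 10-probe features (27.75%) and the 3-probe features (49.67%).

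The rise of the 3-probe class at 144 h was set against technical explanations. With median scaling alone the shift was 0.706 and its lower 95% bootstrap bound was 0.613, which argues against quantile normalization as the whole cause. Between 0 h and 144 h, features with 2 probes shifted by at most 0.088 (upper bound). The lower bound of the 3-probe class was 0.73, which argues against few probes as the whole cause. These bounds come from resampling the features of a class as separate units, with the arrays held fixed. They do not measure the spread between the 2 arrays of a group. From 24 h to 144 h the 2-probe class also shifted higher, by 0.198, against 0.758 for the 3-probe class. Camera gave the 2-probe class a p of 0.000938 over this interval with the preset correlation and 0.0208 with an estimated one. A larger share of structural RNA carried into the labelled 144 h samples could raise the 3-probe class as well. In both replicates 114 of the 151 were higher. Because both 144 h arrays are the amastigote group, such a difference in carried RNA and a biological rise cannot be told apart. The last probe relative to the first, taken here as a sign of RNA quality, was 0.075 and −0.023 at 144 h against 0.205 and 0.215 at 0 h. It was 0.035 and 0.089 at 15 h and 0.099 and 0.036 at 24 h. Most of the fall was thus present at these times, although 144 h replicate 2 was the lowest. The class shift was 0.26 at 15 h and 0.18 at 24 h, against 0.94 at 144 h. This unplanned comparison argues against what the measure captures as the whole cause. Whether RNA quality contributed to the rise is left open.

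The shift of chromosomes 8 and 12 was weighed in the same way. Sets of regions from other chromosomes, matched on brightness, reached a median of at most 0.10 against 0.22 for these chromosomes. This argues against a trend with brightness as the whole cause. The sets were drawn region by region and did not keep the likeness of neighbouring regions. They therefore do not test whether the shift itself exceeds chance, and by camera with an estimated correlation neither chromosome passed (adjusted p of 0.991 for both). On chromosome 12 the upper quartile shifted by 0.211 more than the lower one (95% interval 0.043 to 0.471, blocks of 50000 bp resampled). An even gain of the whole chromosome alone would not give this. The lower quartile of chromosome 12 also shifted up, by 0.194 (0.126 to 0.35). An even gain joined by local change can therefore not be told apart from local change alone. On chromosome 8 the upper quartile shifted by 0.15 more than the lower one, with an interval from −0.155 to 0.629. An even gain cannot be told apart from local change there. Regions correlated with their neighbours across replicates at 0.483 on these chromosomes, above 0.217, the highest of 1000 shuffled orders, which is consistent with runs of neighbouring regions that changed together; whether copy number or RNA level changed was not tested.

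Replicates were more alike across 7.5 h and 10 h than within them. The lower of the crossed correlations exceeded the higher same-time one by 0.061, as an exchange of these times in 1 replicate would give, and this was seen before it was tested. The source name label exchanges them in both replicates, however, and 5 h of replicate 1 with 7.5 h of replicate 2 (0.774) and 7.5 h with 5 h (0.71) also exceeded the same-time values of 0.513 and 0.458. After a correction for feature size the crossed mean stayed 0.194 above the same-time mean, against 0.204 before, which argues against a size trend in single arrays. No biological explanation, such as cultures that progressed at different speeds, was tested.

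Other assignments of the 16 arrays to 8 groups of 2 were drawn. For the F-test, 2 of 100 assignments, the real one included, gave at least the real 1060 features, with 2161 the highest other, and for the transient contrast 3 of 100 gave at least 570, with 1758 the highest other, so that chance assignment by free shuffling can be excluded at 0.05 in both. Each real group holds 1 array of each replicate number, which the shuffled groups did not keep, so variation shared by replicate number or scan day is left out of this comparison. The highest counts point to structure among the arrays; which arrays those assignments grouped was not examined, and likeness of neighbouring times could be part of it.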

How the results depend on the processing

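The scan-day block, the size correction and the fit without the 5, 7.5 and 10 h arrays were chosen after the data were seen. The 76 named results, of which many are 1 region at several times, kept their direction in all 1320 values under alternatives. Part of this was fixed in advance. The replicate block, the trended robust prior, the dim filter and fitting only the arrays compared leave the size of a change as it was. So does exchanging times, for contrasts without those times. Named regions had also been picked for large changes in the same direction in both replicates. Kept direction is therefore a weak test here. Of the 1320 values, 139 missed the threshold or, for transient calls, the same direction against each end. That was most often for regions named at 24 h or as transient with 1 array left out. The mean of probes lowered 14 of the 1320 values by over 1.5-fold, and an offset of 0 raised 2. The 4 named 10-probe features passed in every one run on them. The deposited value table could not be used for named items, regions or chromosomes, and the alternative of 1 list member per product name was not run because no names were paired with IDs. Signal over background limits the dim filter: it removed features under a mean log2 of 7.54 and kept 8127 of 8209. Leaving out 1 array leaves its group with 1, which is then assumed to vary like the other groups. The cause of the changes listed here was not tested, except that stricter thresholds lower counts by construction. Leaving out arrays lowered some counts and raised others.

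Counts for 2.5, 5, 7.5, 10, 15, 24 and 144 h against 0 h were 22, 21, 178, 239, 604, 499 and 2278. An adjusted p under 0.01 gave 9, 10, 45, 27, 89, 78 and 1136, with 172 for 144 h against 24 h, 97 transient, 274 at any time and 283 tiled regions. A log2 change of at least 1 gave 66, 77, 165, 145 and 690 from 7.5 h to 144 h, 259 from 24 h to 144 h, 34 transient, 528 at any time and 298 tiled regions. Which direction had more features turned at 15 h and 24 h with a replicate block (779 higher and 708 lower, 722 and 657), and at 24 h without the 5, 7.5 and 10 h arrays (420 and 411). At 144 h it turned with the trended robust prior (1147 and 1146) and without 144 h replicate 2 (768 and 743). Fitting only the 4 arrays gave 5 at 2.5 h, 0 at 5 h, 23 at 7.5 h, 4 at 10 h and 6 at 24 h.

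Arrays with the same replicate number often deviated together: correlations ran from −0.19 to 0.869 (median 0.518), with 22 of 28 pairs of times over 0.1. As not all did, and the labels state no block, the numbers were not taken as pairs. That the labels call the replicates independent does not settle whether the times of 1 replicate number were. The replicate numbers also follow scan day, so shared variation is left in the model. A replicate block gave 45, 90, 798, 941, 1487 and 1379 from 2.5 h to 24 h, 2247 from 24 h to 144 h, 1446 transient, 2506 at any time and 1649 tiled regions. The scan-day block, by direction, gave 9 higher and 27 lower at 2.5 h, 16 and 44 at 5 h, 239 and 293 at 7.5 h, 388 and 236 at 10 h, 470 and 401 at 15 h and 467 and 409 at 24 h. It gave 868 and 1225 from 24 h to 144 h, 810 and 353 transient, and 1342 tiled regions. The size correction gave 37 at 2.5 h and 33 at 5 h. Without the 6 arrays of 5, 7.5 and 10 h, 831 passed at 24 h and 1660 from 24 h to 144 h. Cyclic loess gave 32 at 5 h, 372 from 24 h to 144 h and 374 transient. The deposited value table gave 13 at 2.5 h and a replicate correlation of 0.717 at 144 h. An estimated correlation left 0 chromosomes by camera, and 0 at an unadjusted p under 0.05. Median scaling moved the median change of all 10-probe features to 0.11 at 10 h.

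With 1 array left out, counts ran from 3 to 8 at 2.5 h, 8 to 17 at 5 h, 18 to 136 at 7.5 h, 19 to 138 at 10 h, 39 to 138 at 15 h, 37 to 103 at 24 h and 1006 to 1511 at 144 h. They ran from 29 to 635 from 24 h to 144 h, 93 to 1051 transient, 294 to 1345 at any time, 219 to 414 tiled regions and 2 to 5 chromosomes. The shift of the 3-probe class kept its direction and its call under every alternative run on it. Exchanging the conflicting times moved no total by over 1.5 times, but the numbers of higher and lower features at 7.5 h and 10 h changed places, and it ended the calls of the chromosome 9 region at 24 h (adjusted p of 0.0502) and the chromosome 29 region from 1003651 as transient (0.0517).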

Other observations

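The correlations of neighbouring regions and the trends with brightness were chosen after the data were seen. Regional timing differed among the strongest changes. The chromosome 27 regions from 859432 to 870220 and from 894116 to 899824 stood at log2 0.05 and 0.13 above 0 h at 2.5 h, 1.24 and 1.60 at 7.5 h and 2.96 and 3.26 at 15 h, while the chromosome 22 region from 250715 to 251909 stood at −0.20, 0.97 and 1.25 at those times and reached 4.02 at 144 h. At 7.5 h replicate 2 was the higher of the 2 in the chromosome 27 region from 894116 (10.05 against 8.28), and replicate 1 in the chromosome 22 region (11.40 against 9.68). The chromosome 15 region from 45723 to 54500 stayed between −0.56 and −0.27 from 2.5 h to 24 h and reached 1.36 at 144 h.

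Over all 8150 pairs of neighbouring tiled regions, changes at 144 h correlated at 0.291, and at 0.23 when the region came from 1 replicate and its neighbour from the other. The highest value of 1000 shuffled orders within chromosomes was 0.0564 (permutation p = 0.000999, one-sided, the smallest these shuffles can give). At 24 h the value across replicates was 0.178.

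The change at 144 h also followed brightness. Its median was 0.22 in the dimmest decile of the 10-probe features and −0.38 in the brightest decile, with quantile normalization. Repeat spots of a probe had a median SD between 0.098 and 0.198 log2 units on an array.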
